A study of Homo sapiens with 10 samples.

How the data were processed

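ChIP-seq with antibodies against ERG or EWS was carried out in 2 human prostate cell lines. VCaP is a prostate cancer line, and RWPE1 is a line from normal prostate that here stably expressed either wild-type ERG or ERG P436A, an ERG with a point mutation at residue 436. Per the labels' protocols, ChIP DNA was sheared to about 150 nucleotides and libraries were size-selected between 200 and 300 nucleotides. Of the 10 samples, 7 ChIP samples had a peak list each, and the 3 input samples (2 of VCaP and 1 of RWPE1) were not used here. The group of each sample came from its label. Wild-type ERG in RWPE1 was the only group with replicate lists, 2 of them, and the labels do not say whether these came from separate cultures.

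Each deposited list holds 3 columns, chromosome, start and end, with no header and no height, fold, score or p-value per peak. The unit of the deposited values is thus a position in base pairs. Reads were aligned with Bowtie2, whose version is given as 0.12.8, to genome build hg19, per the submitters' processing notes. The peak caller, its threshold and the control it used are not given in the sources used here. Each list belongs to 1 sample, so no list is labelled as pooled. Read depth is unknown, and a longer list need not mean more binding. Starts were read as 0-based, since some lists start at 0 on the mitochondrial chromosome, and all positions below are 1-based hg19 positions. Peaks of a list did not overlap each other.

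A peak was counted as shared when at least 1 bp of it overlapped a peak of the other list. Shares carry exact (Clopper-Pearson) 95% binomial intervals. The chance level fixed before the data were examined came from 1000 rotations, in each of which the peaks of every chromosome were moved together around it by a random offset. Its permutation p is one-sided, and the smallest it can give is 0.001. The number of shared peaks over the mean of the rotations is the fold over rotation, with an exact 95% Poisson interval that covers counting error only. A second chance level was added after the lists were seen to have crowded megabases in common: 1000 local shifts, in each of which every peak was moved by 20 to 200 kb in a random direction. Folds over both levels are given, and adjusted p-values (Benjamini-Hochberg) run over the 21 pairs of lists. Shares were compared with Fisher's exact test, two-sided. Ratios of folds were tested with a conditional exact binomial test, two-sided, adjusted over 16 ratios, none of them planned. Peaks are not replicates, so these tests compare lists and not conditions.

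Both chance levels were tested on simulated lists. With 100 shared sites planted between lists the size of the 2 wild-type ERG replicates, the overlap was called by rotation in 20 of 20 draws, and in 0 of 20 with none planted. With the VCaP ERG and EWS lists, rotation called 100 planted sites in 4 of 20 draws, and 0 of 20 with none planted. With lists the size and crowding of VCaP ERG and EWS and no shared site, rotation called 20 of 20 draws with a mean fold of 11.0, while local shifts called 2 of 20 with a mean fold of 1.01. With the crowding of the replicates and no shared site, rotation called 3 of 20 (mean fold 1.82) and local shifts 0 of 20 (mean fold 0.759). The crowded lists were made by the same shifts of 20 to 200 kb, so the low folds and few calls over local shifts were built in. Crowding finer than these shifts was not simulated.

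The planned ranking of peaks by the authors' score was replaced by the order in which the peaks are listed. That order is not documented as a ranking. In the VCaP ERG list peak width fell along the list (Spearman correlation across peaks −0.771), and in the list of ERG replicate 1 as well (−0.655), peaks not being independent replicates. A permutation test with 100000 resamples, two-sided, compared list positions. Up to 10 regions per set were eligible to be named, the first listed of each: VCaP ERG with and without EWS, wild-type ERG with EWS, EWS at wild-type ERG peaks found or not found in the EWS list of P436A cells, and ERG P436A without EWS. Other named regions were chosen after their values were seen. The gene table at hand is of a later human assembly, so no genes, start sites, gene lists or sequence motifs were assigned, and the tests planned on them were not run.

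Megabase bins were called crowded when they held at least 10 peaks of the 2 lists compared. Alternatives were a reciprocal overlap of 0.5, centres within 500 bp, chromosomes 1 to 22 and X, Fisher's exact test over the merged regions of the 7 lists, merged regions of both replicates and leaving out each replicate. Alternatives added after the data were seen were the first listed part of each list, lists of equal length, peaks set to 500 bp, peaks over 2000 bp removed, local shifts, and the same outside crowded bins. Equal length was reached by cutting the longer list in listed order. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.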

Results

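Binding of the ETS transcription factor ERG and of its co-activator EWS was mapped by ChIP-seq in 2 prostate cell lines. VCaP is a cancer line, and RWPE1 is a normal prostate line that here expressed wild-type ERG or ERG P436A. The lists held 7712 ERG and 9500 EWS peaks in VCaP. In RWPE1 with wild-type ERG they held 1901 ERG peaks in replicate 1, 1953 in replicate 2 and 5703 EWS peaks. With ERG P436A they held 1746 ERG and 1786 EWS peaks. Median widths lay between 490 bp (VCaP EWS) and 719 bp (VCaP ERG). The VCaP ERG list had 477 peaks over 2000 bp, the widest of 184765 bp, and each other list had at most 17. No peak was wider than 501 bp in the lists of VCaP EWS, ERG P436A and EWS with P436A. The lists of RWPE1 with wild-type ERG reached 5574 to 7061 bp. Widths thus differed between wild-type and P436A lists and between VCaP ERG and EWS. Whether these lists were called with unlike settings is not known. Groups other than wild-type ERG in RWPE1 had a single list, so differences between them have no replicate check, and depth is unknown.

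In VCaP, 50% of the EWS peaks lay in 77 of 1324 megabase bins with a peak and 50% of the ERG peaks in 171 of 1683. In RWPE1, 50% of a list took from 143 bins (ERG P436A) to 231 (EWS with wild-type ERG), and the most crowded blocks differed between the cell lines. On chromosome 11, the block from 63 to 68 Mb held 704 VCaP ERG and 1072 VCaP EWS peaks, against at most 9 in each RWPE1 list. On chromosome 13, 109 to 112 Mb held 314 VCaP ERG and 292 VCaP EWS peaks, and on chromosome 6, 20 to 21 Mb held 167 and 171. VCaP ERG peaks covered 2123144 bp of the chromosome 13 block and 992602 bp of that on chromosome 11. VCaP EWS peaks covered 142877 bp and 523732 bp of them. In RWPE1, chromosome 1 from 195 to 202 Mb held 162 peaks of ERG replicate 1, 480 of EWS with wild-type ERG, 68 of ERG P436A and 75 of EWS with P436A. The same block held 19 peaks of ERG replicate 2, 3 of VCaP ERG and 0 of VCaP EWS. Chromosomes 1, 5, 9 and 20 carried 47.7% to 57.2% of each RWPE1 list, against 23.7% of VCaP ERG and 12.4% of VCaP EWS peaks.

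**Figure D1:**
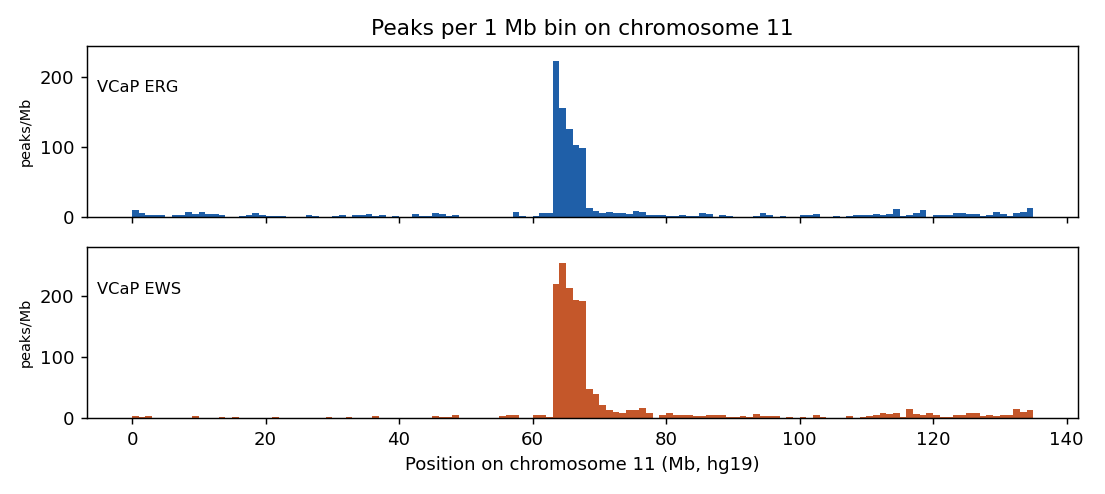
Peaks per 1 Mb bin (vertical axes, peaks per Mb, each panel on its own scale) along chromosome 11 (horizontal axis, Mb, hg19) for VCaP ERG and VCaP EWS. Both lists rise between 63 and 68 Mb, which holds 704 ERG and 1072 EWS peaks.

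**Figure D2:**
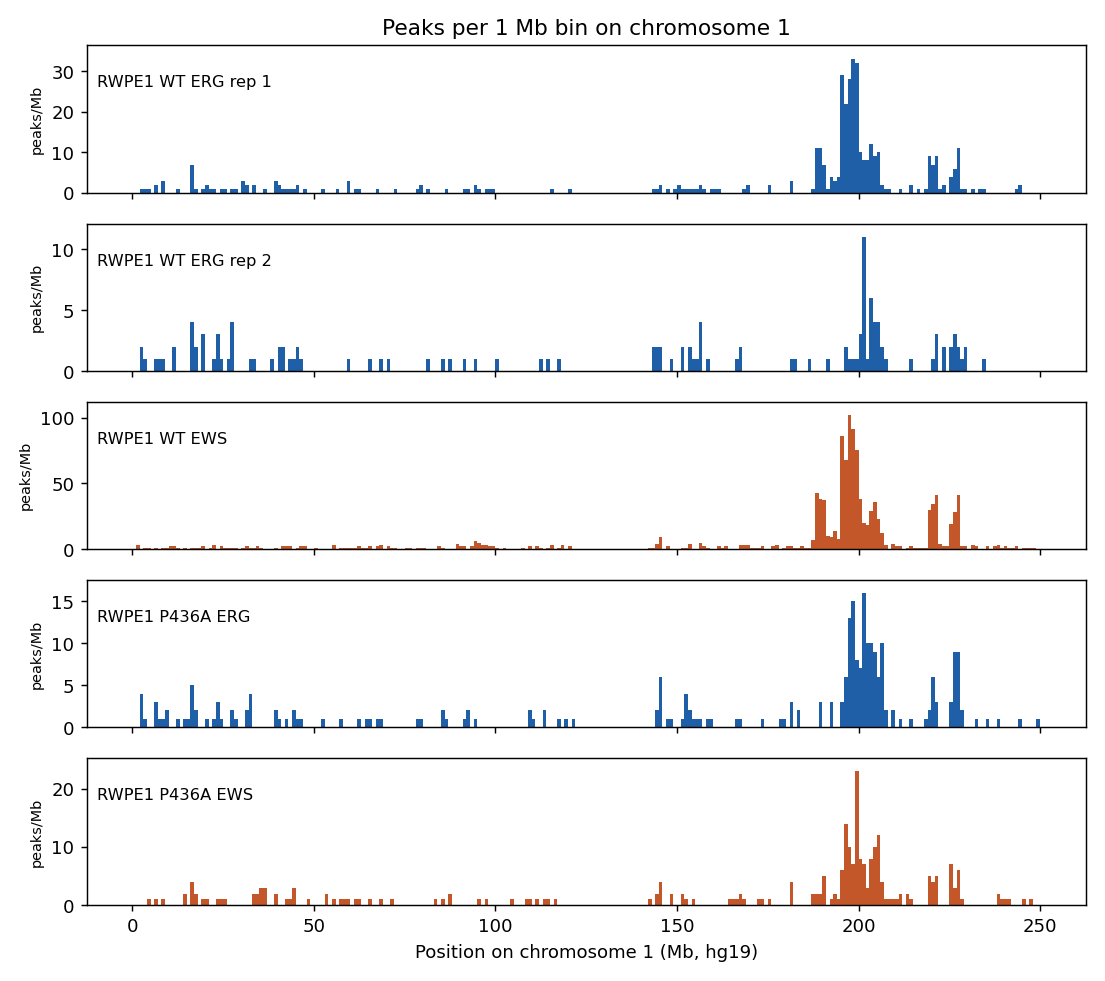
Peaks per 1 Mb bin (vertical axes, peaks per Mb, each panel on its own scale) along chromosome 1 (horizontal axis, Mb, hg19) in the 5 RWPE1 lists. The block from 195 to 202 Mb holds 162 peaks of ERG replicate 1, 19 of ERG replicate 2 and 480 of EWS in cells with wild-type ERG.

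The 2 lists of wild-type ERG in RWPE1 shared few sites. Of the replicate 1 peaks, 115 (6.05%, 5.02% to 7.22%) overlapped a replicate 2 peak, and 116 replicate 2 peaks (5.94%, 4.93% to 7.08%) overlapped one of replicate 1. This was 44.1 times the mean of the rotated lists (36.4 to 53.0; permutation p = 0.001, adjusted p = 0.0011) and 23.3 times that of local shifts (19.2 to 28.0). Among the shared regions, 55 of 115 also had an ERG P436A peak (47.8%, 38.4% to 57.3%) and 21 had a VCaP ERG peak (18.3%, 11.7% to 26.5%). A region of chromosome 19, 13 to 14 Mb, held 59 replicate 2 peaks and 0 of replicate 1.

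Whether the point mutant occupied the sites of wild-type ERG was asked by setting its list against each replicate. ERG P436A peaks were found at 221 replicate 1 peaks (11.6%, 10.2% to 13.2%) and at 133 replicate 2 peaks (6.81%, 5.73% to 8.02%). Neither share lay below that between the wild-type replicates. The fold over rotation was 93.5 (81.6 to 107) with replicate 1 and 45.1 (37.8 to 53.5) with replicate 2, each with permutation p = 0.001, and over local shifts it was 33.7 (29.4 to 38.4) and 18.4 (15.4 to 21.8). Over local shifts, the fold of replicate 1 with ERG P436A was 1.45 times its fold with replicate 2 (1.15 to 1.83; exact adjusted p = 0.00310), whereas the fold of replicate 2 with ERG P436A was 0.791 times its fold with replicate 1 (0.612 to 1.02; exact adjusted p = 0.102). Of the 10 first listed ERG P436A peaks without EWS, 5 were in neither wild-type list, 3 were in replicate 1 only and 2 were in both, at chromosome 1, 199241865 to 199242353, and chromosome 5, 180650442 to 180650926.

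In VCaP, whether EWS was found at ERG sites was asked of the 2 lists. An EWS peak lay at 873 ERG peaks (11.3%, 10.6% to 12.0%), and 975 EWS peaks (10.3%, 9.66% to 10.9%) lay at an ERG peak. Chromosome 11 held 312 of the shared ERG peaks (35.7%), chromosome 13 held 177 and chromosome 6 held 126. The first listed shared regions were at chromosome X, 66850199 to 67034963, chromosome 11, 64080243 to 64087362, and chromosome 13, 111266533 to 111273909. First listed ERG regions without EWS were at chromosome X, 66063045 to 66145392, chromosome 13, 111363060 to 111369034, and chromosome 1, 2186166 to 2188328. The overlap was 15.7 times the mean of rotated lists (14.6 to 16.7; permutation p = 0.001, adjusted p = 0.0011) and 1.50 times that of local shifts (1.40 to 1.60; permutation p = 0.001). Crowded bins held 857 of the 873 shared peaks. Outside them 16 of 2930 ERG peaks (0.546%, 0.312% to 0.885%) had an EWS peak, 2.77 times the mean of local shifts (1.58 to 4.50). With bins called crowded at 5 or at 20 peaks, this fold was 7.20 (3.11 to 14.2) or 2.22 (1.59 to 3.03).

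In RWPE1 with wild-type ERG, the share of ERG peaks with EWS was higher in replicate 1 than in replicate 2, with intervals that did not overlap. EWS peaks lay at 176 replicate 1 peaks (9.26%, 7.99% to 10.7%) and at 63 replicate 2 peaks (3.23%, 2.49% to 4.11%). Regions with EWS that led the replicate 1 list were at chromosome 2, 89874405 to 89875917, chromosome 9, 44070130 to 44071231, and chromosome 16, 33957367 to 33959808, and none of these 3 was in replicate 2. Whether such leading regions hold repeats or DNA from outside the genome, such as a plasmid, was not tested. In replicate 2 the first were at chromosome 12, 6647291 to 6647732, chromosome 9, 91392549 to 91393277, and chromosome 8, 144659378 to 144660158, of which only the chromosome 9 region was also in replicate 1. The fold over rotation was 24.0 (20.6 to 27.8) for replicate 1 and 8.96 (6.88 to 11.5) for replicate 2, each with permutation p = 0.001. Over local shifts the folds were 5.93 (5.09 to 6.88) and 5.78 (4.44 to 7.39) in all bins, and 18.5 (14.1 to 23.9) and 10.1 (6.52 to 14.9) outside crowded bins.

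With ERG P436A, 38 ERG peaks had an EWS peak in the same cells (2.18%, 1.54% to 2.98%). The overlap was 16.3 times that of rotated lists (11.5 to 22.4; permutation p = 0.001) and 7.48 times that of local shifts (5.30 to 10.3), or 14.0 times outside crowded bins (8.79 to 21.2). The EWS list of cells with wild-type ERG, which is longer, had a peak at 86 ERG P436A peaks (4.93%, 3.96% to 6.05%). Its shares were 9.26% of replicate 1 and 3.23% of replicate 2 peaks. The EWS list of P436A cells had a peak at 27 peaks of replicate 1 (1.42%) and 42 of replicate 2 (2.15%), against 2.18% of ERG P436A. For the wild-type replicates these were 11.4 (7.52 to 16.6) and 15.4 (11.1 to 20.8) times rotation. Over local shifts they were 4.69 (3.09 to 6.83) and 9.47 (6.83 to 12.8) times. Overlap with EWS was thus not limited to lists of the same cells. Whether fewer ERG sites had EWS with the mutant was tested for each replicate. The odds of an EWS peak were 4.59 times higher at replicate 1 peaks than at ERG P436A peaks (3.19 to 6.74; Fisher's exact p = 3.36e-21), and 1.50 times at replicate 2 peaks (0.980 to 2.32; Fisher's exact p = 0.0549). With lists of equal length the second value was 0.259 (Fisher's exact p = 5.52e-05), the opposite direction, and with the regions found in both replicates, set against all ERG P436A peaks, it was 6.23 (Fisher's exact p = 1.31e-06). Outside crowded bins the odds ratio was 2.71 for replicate 1 (Fisher's exact p = 3.84e-05), and with equal lengths as well 1.73 (Fisher's exact p = 0.0446). For replicate 2 these values were 1.13 (Fisher's exact p = 0.769) and 0.233 (Fisher's exact p = 8.33e-04). Relative to local shifts in all bins, neither replicate differed detectably from ERG P436A, with ratios of folds of 0.793 (0.556 to 1.16; exact adjusted p = 0.277) and 0.772 (0.508 to 1.19; exact adjusted p = 0.295).

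EWS lists of RWPE1 cells with wild-type and mutant ERG had few sites in common. Of the EWS peaks found with wild-type ERG, 80 (1.40%, 1.11% to 1.74%) overlapped a peak found with ERG P436A, and these made up 4.48% of the latter list (3.57% to 5.54%). The fold was 12.1 over rotation (9.56 to 15.0; permutation p = 0.001) and 4.69 over local shifts (3.72 to 5.84). Against the ERG P436A list, 86 of these wild-type EWS peaks overlapped, 13.1 times rotation (10.5 to 16.2) and 5.20 times local shifts (4.16 to 6.42). Overlap of this size was thus not limited to lists of the same antibody. EWS peaks at a wild-type ERG peak were found with P436A more often than the others: 16 of 222 (7.21%, 4.18% to 11.4%) against 64 of 5481 (1.17%, 0.900% to 1.49%), an odds ratio of 6.57 (3.48 to 11.7; Fisher's exact p = 4.77e-08). Over the alternatives it ran from 4.56 with a reciprocal overlap of 0.5 (7 peaks found again of 169; Fisher's exact p = 0.0016) to 25.7 outside crowded bins (6 of 61; Fisher's exact p = 9.37e-07). Regions found again included chromosome 20, 29588267 to 29589896, chromosome 21, 9825341 to 9828155, and chromosome 20, 62542346 to 62542846. The chromosome 21 region had a peak in every list but VCaP ERG. Whether the regions found again hold repeats, or recur whatever the antibody, was not tested. The odds ratio is thus not shown to reflect EWS kept at sites of ERG binding. Those not found with P436A were led by chromosome 2, 89874544 to 89875919, and chromosome 2, 133025810 to 133031370.

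Between the cell lines, 4.56% to 8.57% of the peaks of each RWPE1 ERG list lay at a VCaP peak of the same factor, and 1.23% to 2.74% of those of each EWS list, a difference that was not tested. VCaP ERG peaks lay at 163 peaks of replicate 1 (8.57%, 7.35% to 9.92%), 89 of replicate 2 (4.56%, 3.68% to 5.58%) and 115 of ERG P436A (6.59%, 5.47% to 7.85%). The folds over local shifts were 11.7 (10.0 to 13.7), 4.90 (3.94 to 6.03) and 7.87 (6.50 to 9.44), and those over rotation 18.5 (15.7 to 21.5), 9.51 (7.64 to 11.7) and 15.6 (12.8 to 18.7). VCaP EWS peaks lay at 70 EWS peaks of cells with wild-type ERG (1.23%, 0.958% to 1.55%), 4.02 times rotation (3.14 to 5.08) and 3.65 times local shifts (2.84 to 4.61). With ERG P436A, 49 EWS peaks had a VCaP EWS peak (2.74%, 2.04% to 3.61%), 9.89 times rotation (7.32 to 13.1) and 7.97 times local shifts (5.89 to 10.5). All of these had permutation p = 0.001. Across cell lines and antibodies, 31 VCaP ERG peaks overlapped an EWS peak of RWPE1 cells with wild-type ERG, 1.19 times rotation (0.810 to 1.69; permutation p = 0.217), and 12 overlapped one of cells with P436A, 1.57 times rotation (0.813 to 2.75; permutation p = 0.106). In the other direction, VCaP EWS peaks lay at 72 ERG peaks of replicate 2 (3.69%, 2.90% to 4.62%), 48 of ERG P436A (2.75%, 2.03% to 3.63%) and 25 of replicate 1 (1.32%, 0.853% to 1.94%). These overlaps were 11.4 times rotation (8.91 to 14.3), 9.44 (6.96 to 12.5) and 3.53 (2.28 to 5.20), and 7.84 times local shifts (6.14 to 9.88), 6.53 (4.81 to 8.66) and 2.30 (1.49 to 3.39), each with permutation p = 0.001. For replicate 2 the share with an EWS peak of VCaP stands beside 3.23% with one of its own cells, and the difference was not tested.

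In VCaP, ERG peaks with EWS stood earlier in the list than those without. Their mean position was 41.8% of the list against 51.0%, a difference of −9.25 percentage points (permutation p = 1e-05, the smallest the resamples can give; adjusted p = 4e-05). The direction turned when peaks were set to 500 bp, with a difference of 3.45 points, and with a reciprocal overlap of 0.5 it was 14.0 points. In RWPE1 the differences were −3.47 points for replicate 1 (permutation p = 0.130), 2.42 for replicate 2 (permutation p = 0.514) and 5.45 for ERG P436A (permutation p = 0.250).

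**Figure D3:**
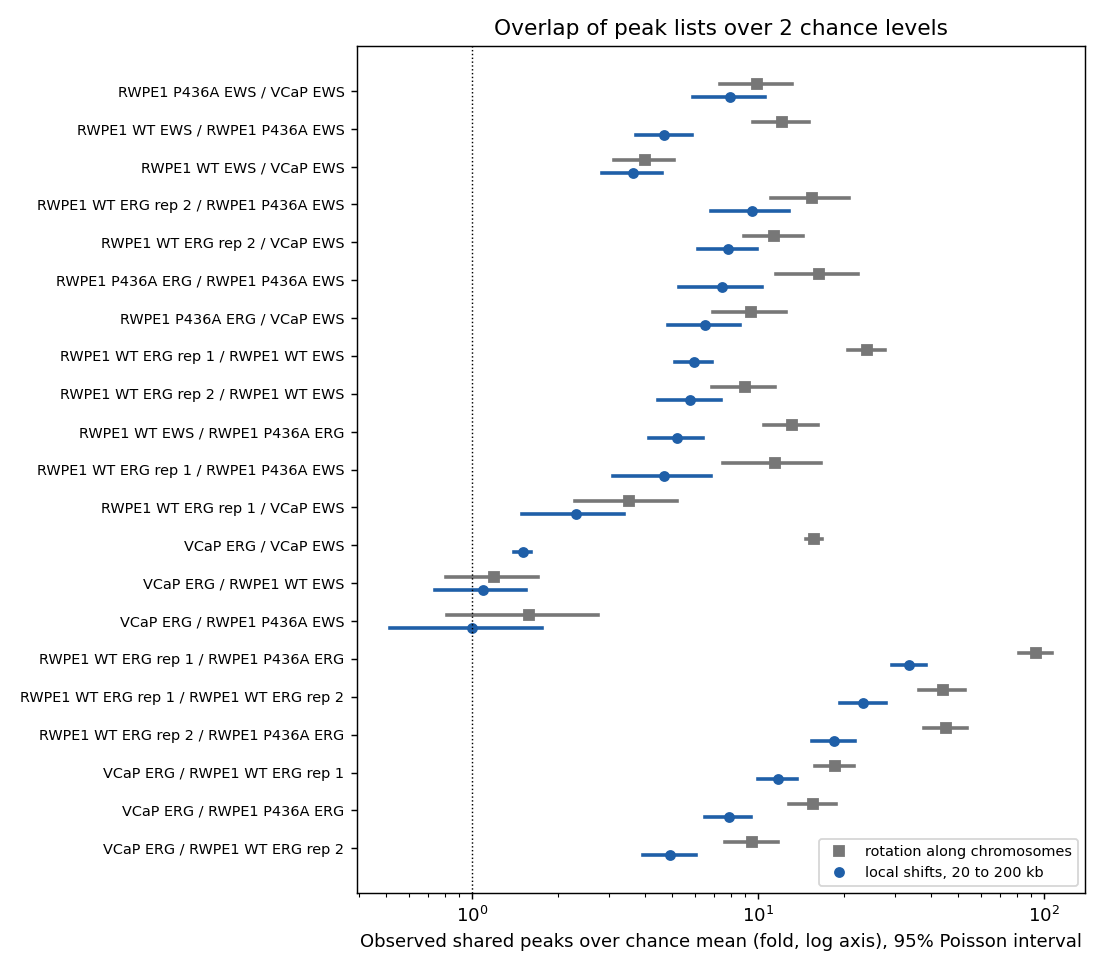
Shared peaks over the chance mean (horizontal axis, fold, log scale) for the 21 pairs of lists, with squares for rotation, circles for local shifts and lines for 95% Poisson intervals (WT, wild-type ERG). The VCaP ERG and EWS pair moves from 15.7 over rotation to 1.50 over local shifts, and ERG replicate 1 with ERG P436A is highest on both.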

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

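Tests on peak width in VCaP, on list length and width for the ERG replicates, and on the longer EWS list were set before their results were seen, and the other tests and the ratios of folds below were chosen after. Of 16 ratios of folds between lists, 10 differed from 1 after adjustment. Over rotation, the ERG and EWS overlap with wild-type ERG was 1.47 times that with P436A for replicate 1 (exact adjusted p = 0.0491) and 0.549 times for replicate 2 (exact adjusted p = 0.0107), in opposite directions. With the EWS list of wild-type cells for both ERG forms, the ratios were 1.83 for replicate 1 (exact adjusted p = 9.65e-06) and 0.682 for replicate 2 (exact adjusted p = 0.0384) over rotation, but 1.14 (0.877 to 1.49; exact adjusted p = 0.382) and 1.11 (0.790 to 1.56; exact adjusted p = 0.595) over local shifts. VCaP was at 0.653 times replicate 1 (exact adjusted p = 3.27e-06) and 1.75 times replicate 2 (exact adjusted p = 1.26e-05) over rotation. Over local shifts it was at 0.252 (exact adjusted p = 4.65e-45) and 0.259 (exact adjusted p = 3.94e-17). The overlap of replicate 1 with ERG P436A was 2.12 times that with replicate 2 over rotation (exact adjusted p = 1.26e-10) and 1.45 times over local shifts (exact adjusted p = 0.00310). Both overlaps were counted on the same replicate 1 peaks, 54 of which had both, and the test ignores this pairing. The odds ratio of 4.59 for an EWS peak at replicate 1 over ERG P436A peaks (Fisher's exact p = 3.36e-21) compares these lists and not the groups, as replicate 2 gave 1.50 (Fisher's exact p = 0.0549).

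The overlap of ERG and EWS in VCaP was 15.7 times rotation. Crowding of both lists into the same megabases accounts for much of this, as 1.50 times remained over local shifts (1.40 to 1.60). Those shifts also break up clusters finer than 20 kb and the edges of crowded blocks. The remaining 1.50 therefore cannot tell shared sites from finer crowding. Local shifts called 2 of 20 simulated crowded pairs without shared sites, but those pairs were made by the same shifts. With all peaks at 500 bp, the ERG peaks with EWS fell from 873 to 544, at 1.59 times local shifts (1.46 to 1.72). With peaks over 2000 bp removed, 602 of 7235 had EWS. Local shifts keep the width of each peak, so wide peaks raise the observed and chance counts together. The fold therefore cannot decide how far wide ERG peaks set the overlap. VCaP ERG peaks found in an RWPE1 ERG list had lower odds of EWS, at 0.396 (0.218 to 0.669, Fisher's exact p = 1.33e-04). Within crowded bins the odds ratio was 0.497 (0.263 to 0.870), and outside them 1.13 (0.0267 to 7.45), with EWS at 1 of 163 such peaks. Crowded bins held 857 of the 873 shared peaks, and the most crowded blocks differed between the lines. These odds therefore cannot decide whether EWS marks the sites ERG occupies in both lines. Copy number in VCaP was not tested, as input reads were not used here.

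ERG replicate 1 shared few peaks with replicate 2 and more with ERG P436A. The ERG P436A list was shorter than that of replicate 2, with 1746 against 1953 peaks, and its peaks were at most 501 bp wide. Neither its length nor its width would thus raise its overlap with replicate 1. With lists of equal length and 500 bp peaks the ratio of folds was 1.35 (1.05 to 1.73, exact p = 0.0158). A fold over local shifts already allows for length and width, and the cut follows list order, so this ratio adds little. Many listed peaks may lie near the calling threshold: the first 381 replicate 1 peaks were found in replicate 2 at 3.53 times the odds of the last 380 (1.96 to 6.62; Fisher's exact p = 4.69e-06). This rests on list order, which is not documented as a ranking, and does not by itself account for the larger overlap with P436A. Peak width also fell along the replicate 1 list (Spearman correlation across peaks −0.655). Wider early peaks could give the same result, and this odds ratio cannot tell the explanations apart. No biological explanation was tested.

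A larger share of replicate 1 than of ERG P436A peaks had EWS. At equal lengths the odds ratio was 2.73 (1.85 to 4.10, Fisher's exact p = 7.26e-08). That cut kept the first listed peaks. Of the first 100 EWS peaks with wild-type ERG, 41 lay at a replicate 1 peak, against 3.03% of the whole list. The cut therefore cannot decide whether the longer EWS list is the whole cause. With the EWS list of P436A cells for both, the shares were 1.42% of replicate 1 and 2.18% of ERG P436A peaks, the opposite direction. Outside crowded bins the odds ratio was 2.71 (1.62 to 4.67, Fisher's exact p = 3.84e-05). Local shifts there gave a mean of 3.19 for 1229 replicate 1 peaks and 1.57 for 1204 ERG P436A peaks. Chance was thus still unequal, and this odds ratio cannot decide whether crowding alone is the cause. List length and crowding together stay open, with an odds ratio of 1.73 (1.01 to 3.05, Fisher's exact p = 0.0446). The ratio of folds over local shifts was 0.793 in all bins (0.556 to 1.16). Outside crowded bins the folds were 18.5 (14.1 to 23.9) for replicate 1 and 14.0 (8.79 to 21.2) for ERG P436A. These depend on the cut, with 23.5 and 22.1 when bins were called crowded at 5 peaks, and 14.2 and 8.90 at 20 peaks. The ERG form cannot be told apart from list length and crowding, nor from untested copy number, repeats or foreign DNA in the RWPE1 lists. The same form in replicate 2 gave 1.50 (0.980 to 2.32), and each form had 1 EWS list.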

How the results depend on the processing

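Local shifts, list order, equal lengths, 500 bp peaks, removal of wide peaks and crowded bins were chosen after the data were seen. Over 18 results with a test, 154 of 171 alternatives kept the direction and the side of the threshold, which says little of size: most permutation p-values lie at their floor, and 43 of 116 folds other than Fisher's moved by over 1.5 times, 20 down and 23 up, VCaP ERG and EWS from 15.7 to 1.50 over local shifts. The 7 lists held no overlapping peaks, so merging them tested nothing. Fisher's exact test over the merged regions of all lists reversed 9 overlaps: 0.850 for the wild-type ERG replicates, 0.175 for VCaP ERG and EWS, 0.375 and 0.122 for ERG replicates 1 and 2 with EWS, 0.337 for ERG and EWS with P436A, 0.173 for the 2 RWPE1 EWS lists, 0.230 and 0.115 for ERG replicates 1 and 2 with VCaP ERG, and 0.0179 for EWS between the lines; replicate 2 with ERG P436A fell to 1.13. Construction shows the cause, since of 27928 merged regions 25905 were in only 1 list, and none is a site without a peak. The odds ratio of replicate 2 over ERG P436A reversed to 0.685 in the first listed part, 0.259 at equal lengths and 0.233 at equal lengths outside crowded bins, and passed the threshold at 6.23 with regions of both replicates; the cause was not tested. The VCaP list position reversed to 14.0 with reciprocal overlap, 3.36 with centres within 500 bp and 3.45 with 500 bp peaks, as wide peaks come first. Without replicate 1 the odds ratio for EWS peaks found again with P436A was 9.53, and without replicate 2 it was 5.99. Removing regions in all 7 lists moved nothing, as there were 0. Alternatives on start sites, motifs, genes and the authors' ranking column were not run. No paired analysis was possible because only 1 group has replicate lists. Depth is unknown, so a site missing from a list is not shown to be unbound.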

Other observations

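The regions below were chosen after the data were seen, and no explanation was tested for them. In 15 places a VCaP ERG peak had a peak in all 3 RWPE1 ERG lists, among them chromosome 1, 2186166 to 2188328, chromosome 5, 158689590 to 158690988, chromosome 9, 130213174 to 130214313, and chromosome 17, 79818265 to 79819679. An EWS peak of any list lay at 3 of the 15. All 3 EWS lists had a peak in 7 merged regions, among them chromosome 21, 9825341 to 9828169, chromosome 5, 124121151 to 124121940, and chromosome 9, 68413403 to 68420479. In replicate 2, ERG peaks found in another ERG list had EWS more often than the rest (8.56% against 2.42%; odds ratio 3.78, 2.10 to 6.62; Fisher's exact adjusted p = 7.26e-05), and in replicate 1 they did not detectably differ (7.92% against 9.62%; odds ratio 0.808, 0.524 to 1.22; Fisher's exact adjusted p = 0.434). In ERG P436A the shares were 3.72% and 1.75% (odds ratio 2.17, 1.03 to 4.42; Fisher's exact adjusted p = 0.0655).

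Several lists opened with the same small windows. Chromosome 22, 29669209 to 29696296, held 7 peaks of ERG replicate 2, all among its first 10, and 4 peaks of EWS with P436A, at positions 2 to 6. It also held 3 peaks of ERG P436A and 3 of VCaP EWS, and 0 of ERG replicate 1, EWS with wild-type ERG and VCaP ERG. Windows at chromosome 2, 89852630 to 89880229 and 133011693 to 133031578, led the lists of ERG replicate 1 and of EWS with wild-type ERG and held no peak of ERG replicate 2, ERG P436A or EWS with P436A. Of the first 20 EWS peaks with wild-type ERG, 19 lay at an ERG peak of replicate 1, 0 at one of replicate 2 and 1 at one of ERG P436A. Whether these windows hold repeats, plasmid or carried-over DNA was not tested, so their overlaps are not shown to be sites of binding. In VCaP, 96 of the first 100 EWS peaks lay at an ERG peak, while 30 of the first 100 ERG peaks lay at an EWS peak. ERG peaks there reached 184765 bp and EWS peaks at most 501 bp, so several EWS peaks can lie in a single ERG peak. How far this sets the counts was not tested, and list order is not documented as a ranking. Chromosome X from 66713905 to 67058707 held 5 VCaP ERG peaks, 3 of them among the first 20, 2 VCaP EWS peaks and none of the RWPE1 lists.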
